A study of Homo sapiens with 4 samples.

How the data were processed

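Total RNA from cultured human mammary luminal progenitor cells was labelled with biotin and hybridised to one-colour Affymetrix Human Gene 1.0 ST arrays, per the labels' protocols. The labels gave 2 arrays of cells with a control hairpin and 2 arrays of cells with a hairpin against MEN1, and groups and replicate numbers were taken from the sample titles. Scanner files were not used here. The value table that the authors deposited holds log2 expression values, as judged from its range (2.13 to 14.26 over the 4 arrays). The authors used Affymetrix Power Tools, per the submitters' processing notes. The version, the summarisation method and the normalization between arrays are not given in the sources used here, and neither is a background level for the probes. All 4 value columns were matched to samples, and the values were used as deposited, without further normalization or a filter on dim rows. All 4 arrays held different values.

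The table has 33297 rows. In the platform annotation 19460 rows name 1 gene symbol, 1754 name several and 12083 are not listed. Of the rows with 1 symbol, 19429 had an Entrez identifier found in the NCBI RefSeq gene table, and 0 symbols changed by it. No coordinates were used, since the table names no genome build. For each gene the row with the highest mean over all arrays was kept among rows naming 1 gene, which gave 18417 genes. Of these, 769 had more than 1 row, and in 3 the rows disagreed in sign by over 0.2 each way (log2). Some transcript families share probes, so the members of the SPRR2 and histone families are uncertain as single genes.

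Differences are MEN1 shRNA minus control shRNA, so that a positive value is higher in MEN1 shRNA. They were fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3) with the group as the only term, leaving 2 residual degrees of freedom and 3.57 prior degrees of freedom. P-values were two-sided, adjusted by Benjamini-Hochberg over 18417 genes, with a threshold of 0.05. A gene was said not to overlap when each array of a group lay beyond both arrays of the other. In 35 gene lists with at least 5 measured members, the shift was tested with limma's camera at a preset correlation of 0.01, adjusted over the 35 lists. Camera with an estimated correlation and fry were alternatives. With the estimated correlation 0 of the 17 calls held. In the simulation described below it called 0 of 5 lists shifted by 0.5, so a lost call does not show that a list did not shift. Fry tests whether a list's genes move one way on balance, without comparing them with other genes. Of the 820 different genes in the lists, 69 had no row naming that gene alone.

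The lists, the tests and the rule for named genes were fixed before the data were examined. They cover menin partners and reported targets, mammary cell types, fibroblasts and other cells, interferon and inflammation, cell cycle and arrest, signalling pathways, metabolism and stress. The rule names MEN1, the 12 most positive and the 12 most negative genes among those past the threshold without overlap, and the 4 members of each list with the largest absolute difference. Where fewer than 12 passed in a direction, places were filled with genes at least 1.5-fold different without overlap that had the smallest unadjusted p, stated as not passing. Rows naming several genes, Y-linked genes, XIST, genes deleted in part of the population, and HLA, immunoglobulin and T-cell receptor genes were never named. Genes named outside the rule are said to be chosen after their values were seen.

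The steps were tested on simulated data with 18417 genes, spreads drawn from the prior that limma fitted to these arrays, and 200 changed genes in each of 5 runs. In this comparison 56.7% of genes changed by 0.5 on the log2 scale were called, 96.7% of those changed by 1 and 98.5% of those changed by 1.5. Of all calls, 4.11% were unchanged genes. Genes were simulated independently, so the list results do not cover lists whose genes vary together. Camera with the preset correlation called 5 of 5 lists of 25 genes shifted by 0.5, fry 4 and camera with an estimated correlation 0, and each called 0 of 170 unchanged lists.

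The alternatives were an intensity trend or a robust prior in eBayes, quantile normalization, centring of each array on its median, filters on dim genes, the mean of a gene's rows, the replicate number as a block, leaving out each array, other thresholds and the other list tests. A fit over all rows of the table, with and without the trend, and lists without shared genes were added after seeing the data.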

Results

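Gene expression was measured on Affymetrix Human Gene 1.0 ST arrays, which read each transcript with probes along its length, in cultured human mammary luminal progenitor cells. These are epithelial cells of the milk-forming layer of the breast, sorted from normal tissue by the surface proteins CD49f and EpCAM. The cells had been infected with lentivirus carrying a short hairpin RNA (shRNA) against MEN1, or a control hairpin, and selected with puromycin. MEN1 encodes menin, a tumour suppressor and scaffold of histone methyltransferase complexes. The design asked which genes differ after MEN1 silencing. There were 2 MEN1 shRNA arrays and 2 control shRNA arrays, and the small number of arrays limits the precision. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The median log2 value over all 33297 rows lay between 7.20 and 7.24 on the 4 arrays. Over the 18417 genes tested, the arrays of a group differed at least 1.5-fold in 25 genes (control shRNA) and 17 genes (MEN1 shRNA), and arrays of different groups in 93 to 126 genes.

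MEN1 mRNA was lower in both MEN1 shRNA arrays than in both control arrays, by a small amount. Its log2 value was 9.06 ± 0.011 (SD, n = 2) in control shRNA and 8.76 ± 0.0012 (SD, n = 2) in MEN1 shRNA. The difference of -0.30 (SE 0.052) had a 95% interval from -0.43 to -0.17 and corresponds to a level 18.6% lower. It did not pass the threshold over all genes in limma (adjusted p = 0.125), and did with an intensity trend in the variance (adjusted p = 0.0140), with a range from 0.0122 to 0.533 over the settings tried. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333.

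MMP3, CXCL5, DCN and GREM1 were the genes with the largest rises that passed the test, and most genes that passed were higher in MEN1 shRNA. Of 18417 genes, 67 rose and 6 fell at an adjusted p under 0.05 in limma, all 73 without overlap between the groups. Of the 67 that rose, 38 were in none of the gene lists fixed beforehand. MMP3, the matrix protease stromelysin, rose 2.91-fold, from 8.91 ± 0.11 to 10.45 ± 0.028 (log2, SD, n = 2), and the neutrophil chemokine CXCL5 rose 2.86-fold, from 9.29 ± 0.093 to 10.81 ± 0.085. The small matrix proteoglycan DCN rose 2.74-fold (log2 difference 1.45, SE 0.080), and GREM1, a secreted inhibitor of bone morphogenetic proteins, rose 2.58-fold (1.37, SE 0.082). The cytokine IL6 rose by 1.23 (SE 0.070) and the soluble pattern recognition protein PTX3 by 1.31 (SE 0.13). ABI3BP (2.43-fold), COL10A1 (2.31-fold), SRGN (2.30-fold), DPP4 (2.30-fold), CCDC80 (2.22-fold) and ANKRD1 (2.12-fold) completed the 12 highest that passed. The adjusted p-values of the 12 lay between 0.0126 and 0.0336 in limma. COL10A1 is a collagen, SRGN the proteoglycan serglycin of secretory granules, and DPP4 a cell surface peptidase.

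The 6 genes that fell changed less. CCDC3 fell by 0.68 (SE 0.053), which is 1.60-fold, and the sorting receptor SORL1 fell by 0.55 (SE 0.053). The glucose transporter SLC2A3 and the selenium carrier SELENOP each fell by 0.52 (SE 0.054). The imprinted gene PEG10 fell by 0.50 and the secreted guidance protein SEMA3D by 0.46, the smallest size that passed the test. The adjusted p-values of the 6 lay between 0.0193 and 0.0472 in limma. Of genes at least 1.5-fold lower without overlap, EYS (-0.74), APOBEC3G (-0.62), SNORD20 (-0.79), OR52K3P (-0.72), OR6B2 (-0.65) and LIMD1-AS1 (-0.74) did not pass the test. Their adjusted p-values ran from 0.113 to 0.578. In all, 81 genes were at least 1.5-fold higher and 7 at least 1.5-fold lower without overlap. In 41.5% of genes the groups did not overlap in either direction, against 33.3% by chance.

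**Figure D1:**
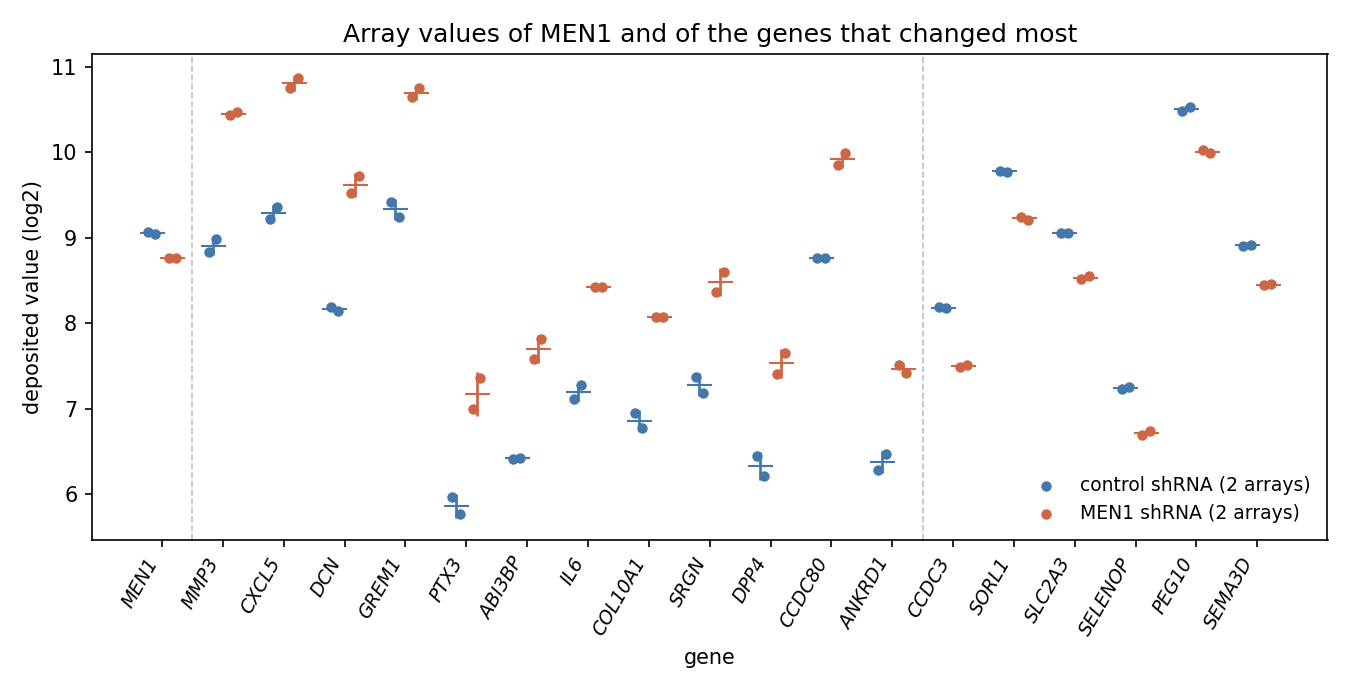
Deposited log2 value (vertical axis) on each of the 2 control shRNA and 2 MEN1 shRNA arrays. Drawn are MEN1 and, among genes that passed the test, the 12 that rose most and the 6 that fell. Points are arrays, horizontal marks are group means and vertical bars are 1 SD. The groups do not overlap for any gene drawn, and MEN1 differs by -0.30 against 1.54 for MMP3.

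The counts of changed genes moved with how the variance was modelled and with single arrays. With an intensity trend limma called 340 genes higher and 162 lower, and in a fit over all 33297 rows, chosen after seeing the data, it called 0 (unadjusted p under 0.05 for 788 higher and 650 lower). Without control shRNA replicate 1 the counts were 5 higher and 1 lower, and without control shRNA replicate 2 they were 11 and 0 (864 lower at an unadjusted p under 0.05). Without MEN1 shRNA replicate 1 or replicate 2 limma called 0 genes, with 737 higher and 559 lower, and 749 higher and 546 lower, at an unadjusted p under 0.05. Of the 13 fibroblast and 8 inflammatory genes described next, 0 and 3 passed without control shRNA replicate 1, 1 and 5 without control shRNA replicate 2, and 0 and 0 without either MEN1 shRNA array. The 73 genes kept their direction in each of these fits, but the fits could not have reversed it. Their groups did not overlap, so leaving out an array keeps the sign. The trend and the fit over all rows do not change the differences.

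Genes of fibroblasts, the matrix-producing cells of connective tissue, formed the group with the largest shift. Of 25 measured members, 13 rose, 0 fell and 12 did not pass; adjusted over the list alone, 21 were higher and 1 was lower. The median log2 difference was 0.66. DCN (1.45), the proteoglycan LUM (1.06), the matrix protein POSTN (0.98) and the microfibril gene FBN1 (0.98) differed most, and all 4 rose. The list was called higher by limma's camera (adjusted p = 1.6e-28), and not with an estimated correlation (adjusted p = 0.354 with an estimated correlation). That alternative called 0 of 5 simulated lists shifted by 0.5. A call lost with it, here or below, therefore does not show that a list did not shift. The estimated correlation was 0.19 for fibroblast and 0.23 for mitosis genes, against the preset 0.01. Over the lists it ran from -0.044 (estrogen response) to 0.63 (replication-dependent histones). Where genes vary together more than the preset allows, camera's p-values here and below are too small. The simulation drew genes independently and does not cover this. Markers of other non-epithelial cells did not shift as groups in camera. Few lay above the median gene in control arrays (2 of 14 endothelial, 4 of 17 leukocyte and 1 of 11 adipocyte, against 13 of 25 fibroblast). A shift of dim markers could be missed. The median difference was 0.0079 for 14 endothelial markers (adjusted p = 0.960), -0.016 for 17 leukocyte markers (adjusted p = 0.430) and -0.012 for 11 adipocyte markers (adjusted p = 0.702). Of their members, LCP1, an actin-bundling protein of leukocytes, rose (0.93). Adjusted over each list alone, LCP1 was higher and the endothelial receptor KDR was lower (-0.48).

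Inflammatory cytokine genes rose as a group beside the fibroblast genes. Of 32 members, 8 rose, 0 fell and 24 did not pass, and 17 were higher when adjusted over the list alone. MMP3 (1.54), CXCL5 (1.52), IL6 (1.23) and the collagenase MMP1 (1.08) led the list, and the median was 0.20 (camera, adjusted p = 3.3e-21; adjusted p = 0.354 with an estimated correlation). The senescence list rose too (median 0.21, camera, adjusted p = 1.0e-11; adjusted p = 0.354 with an estimated correlation). Its 4 members that rose (MMP3, IL6, MMP1 and the neutrophil chemokine CXCL8) are all in the inflammatory list, and 9 of 14 were higher when adjusted over the list alone. Without the genes shared with the fibroblast or inflammatory list, a comparison chosen after seeing the data, its other 9 genes were still called higher (median 0.15, camera, adjusted p = 0.00069). Among extracellular proteases and matrix genes, MMP3, MMP1, fibronectin (FN1, 0.66) and MMP10 (0.65) rose, 4 of 22, while adjusted over the list alone 8 were higher and 3 lower. That list was called higher with a median of 0.045 (camera, adjusted p = 0.0017; adjusted p = 0.354 with an estimated correlation). It was not called without those shared genes (19 genes, adjusted p = 0.228). Interferon response genes moved less, and fry did not call them (adjusted p = 0.117). Of 36, 1 rose (SAMD9L, 0.46) and 3 were higher when adjusted over the list alone, with IFI6 at 0.33, SAMD9 at 0.32 and a list median of 0.021 (camera, adjusted p = 0.0171; adjusted p = 0.362 with an estimated correlation). That call was lost without MEN1 shRNA replicate 1 (adjusted p = 0.0935).

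Genes of mesenchymal transition and of the response to TGF-beta were higher, with few single genes past the threshold. The cell adhesion gene CDH2 (1.03), the transcription factor ZEB1 (0.80) and FN1 (0.66) rose among 20 mesenchymal genes, where MMP2 was at 0.46 without passing. FN1 and MMP2 are also in the fibroblast list. Adjusted over the list alone 8 were higher and 1 lower, and the median was 0.14 (camera, adjusted p = 2.0e-06; adjusted p = 0.370 with an estimated correlation). Without the genes shared with the fibroblast or inflammatory list, the other 16 were called higher with a median of 0.068 (camera, adjusted p = 0.0028). Of 26 genes of the TGF-beta response, FN1 and the protease MMP10 rose, with the actin-binding TAGLN at 0.64 and MMP9 at 0.55 not passing. Adjusted over the list alone 11 were higher, and the median was 0.14 (camera, adjusted p = 1.7e-09; adjusted p = 0.354 with an estimated correlation). Without the shared genes the median of the other 24 was 0.13 (camera, adjusted p = 2.3e-07). Fry called the full TGF-beta list higher (adjusted p = 0.0334) and did not call the full mesenchymal list (adjusted p = 0.0607).

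Genes of keratinocyte differentiation and of sterol synthesis were each called higher as lists with 0 members past the threshold over all genes in limma. The keratinocyte genes CDSN (0.69), SPRR2G (0.64) and LCE3D (0.55), outside the list and chosen after their values were seen, did pass. Fry did not call the keratinocyte (adjusted p = 0.123), cholesterol synthesis (adjusted p = 0.0570) or oxidative stress list (adjusted p = 0.0570). Among 29 keratinocyte genes, SPRR2A, a precursor of the cornified envelope, differed by 1.23, SPRR2D by 0.85, S100A12 by 0.78 and SPRR3 by 0.75. Adjusted over the list alone 7 were higher, and the median was 0.13 (camera, adjusted p = 2.3e-07; adjusted p = 0.407 with an estimated correlation). Of 19 cholesterol synthesis genes, 17 had a positive difference, with HMGCS1 at 0.40, SC5D at 0.31, SQLE at 0.27 and TM7SF2 at 0.26, and 4 were higher when adjusted over the list alone. The median was 0.16 (camera, adjusted p = 7.9e-09; adjusted p = 0.354 with an estimated correlation). Oxidative stress genes had a median of 0.10, with HMOX1 at 0.45 and AKR1C1 at 0.37, and 6 of 20 higher when adjusted over the list alone (camera, adjusted p = 0.0018; adjusted p = 0.354 with an estimated correlation).

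Cell division genes were lower together by small amounts, and the list calls below were made by camera and not by fry. Fry gave adjusted p-values of 0.0957 for mitosis, 0.0957 for G1/S and 0.215 for histone genes. For the unfolded protein response it gave 0.0607 and for the menin complex 0.0651. All 45 mitosis genes had a negative difference, 39 of them without overlap. Over all 18417 genes 4170 were lower without overlap, where chance gives 1 in 6, and genes of a list can vary together. CCNB2 and ASPM were at -0.25, PBK at -0.22 and NUF2 at -0.21, with a median of -0.14 (camera, adjusted p = 2.2e-13; adjusted p = 0.354 with an estimated correlation). Of 35 G1/S genes 30 were negative, with CLSPN at -0.28 and the replicative helicase subunit MCM2 at -0.24, and the median was -0.13 (camera, adjusted p = 3.2e-06; adjusted p = 0.354 with an estimated correlation). Of 28 replication-dependent histone genes 26 were negative, with H2AC14 at -0.45 and H1-5 at -0.28, and the median was -0.13 (camera, adjusted p = 2.4e-07; adjusted p = 0.523 with an estimated correlation). No member of these 3 lists passed over all genes or when adjusted over the list alone. The 29 genes of the unfolded protein and amino acid response had a median of -0.080 with 0 members past either threshold, and PSAT1 (-0.32) and PHGDH (-0.24), enzymes of serine synthesis, differed most (camera, adjusted p = 0.0019; adjusted p = 0.354 with an estimated correlation). The menin complex list, which holds MEN1 itself, was called lower with a median of -0.082 over 10 genes (camera, adjusted p = 0.0188; adjusted p = 0.448 with an estimated correlation). MEN1 was the member lower when adjusted over the list alone, and PSIP1 was at -0.18. The call was lost without MEN1 shRNA replicate 1 (adjusted p = 0.149) and without control shRNA replicate 2 (adjusted p = 0.0574).

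Markers of luminal cells were not lower as groups. Fry did not call the luminal progenitor (adjusted p = 0.0555) or the pan luminal list (adjusted p = 0.173). The 25 luminal progenitor markers had a median of 0.053, with 0 past the threshold over all genes and 4 higher when adjusted over the list alone, led by S100A9 (0.45), CLDN1 (0.29) and RARRES1 (0.27). The list was called higher (camera, adjusted p = 0.0126; adjusted p = 0.354 with an estimated correlation). It was lost without MEN1 shRNA replicate 2 (adjusted p = 0.0643). The 16 pan luminal genes had a median of 0.040, 0 past either threshold, and ESRP2 at 0.23 (camera, adjusted p = 0.0403; adjusted p = 0.521 with an estimated correlation). That call was lost without control shRNA replicate 1 (adjusted p = 0.413), without MEN1 shRNA replicate 1 (0.0645) or replicate 2 (0.133), with median centring (0.0625) and with the mean of a gene's rows (0.0723). The 23 mature luminal markers, with CA12 at -0.21, had a median of 0.024 and 0 past either threshold, and the list was not called (camera, adjusted p = 0.596). The 22 basal and myoepithelial markers had a median of 0.0029, with 1 higher when adjusted over the list alone (TAGLN, 0.64), and were not called (camera, adjusted p = 0.451).

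**Figure D2:**
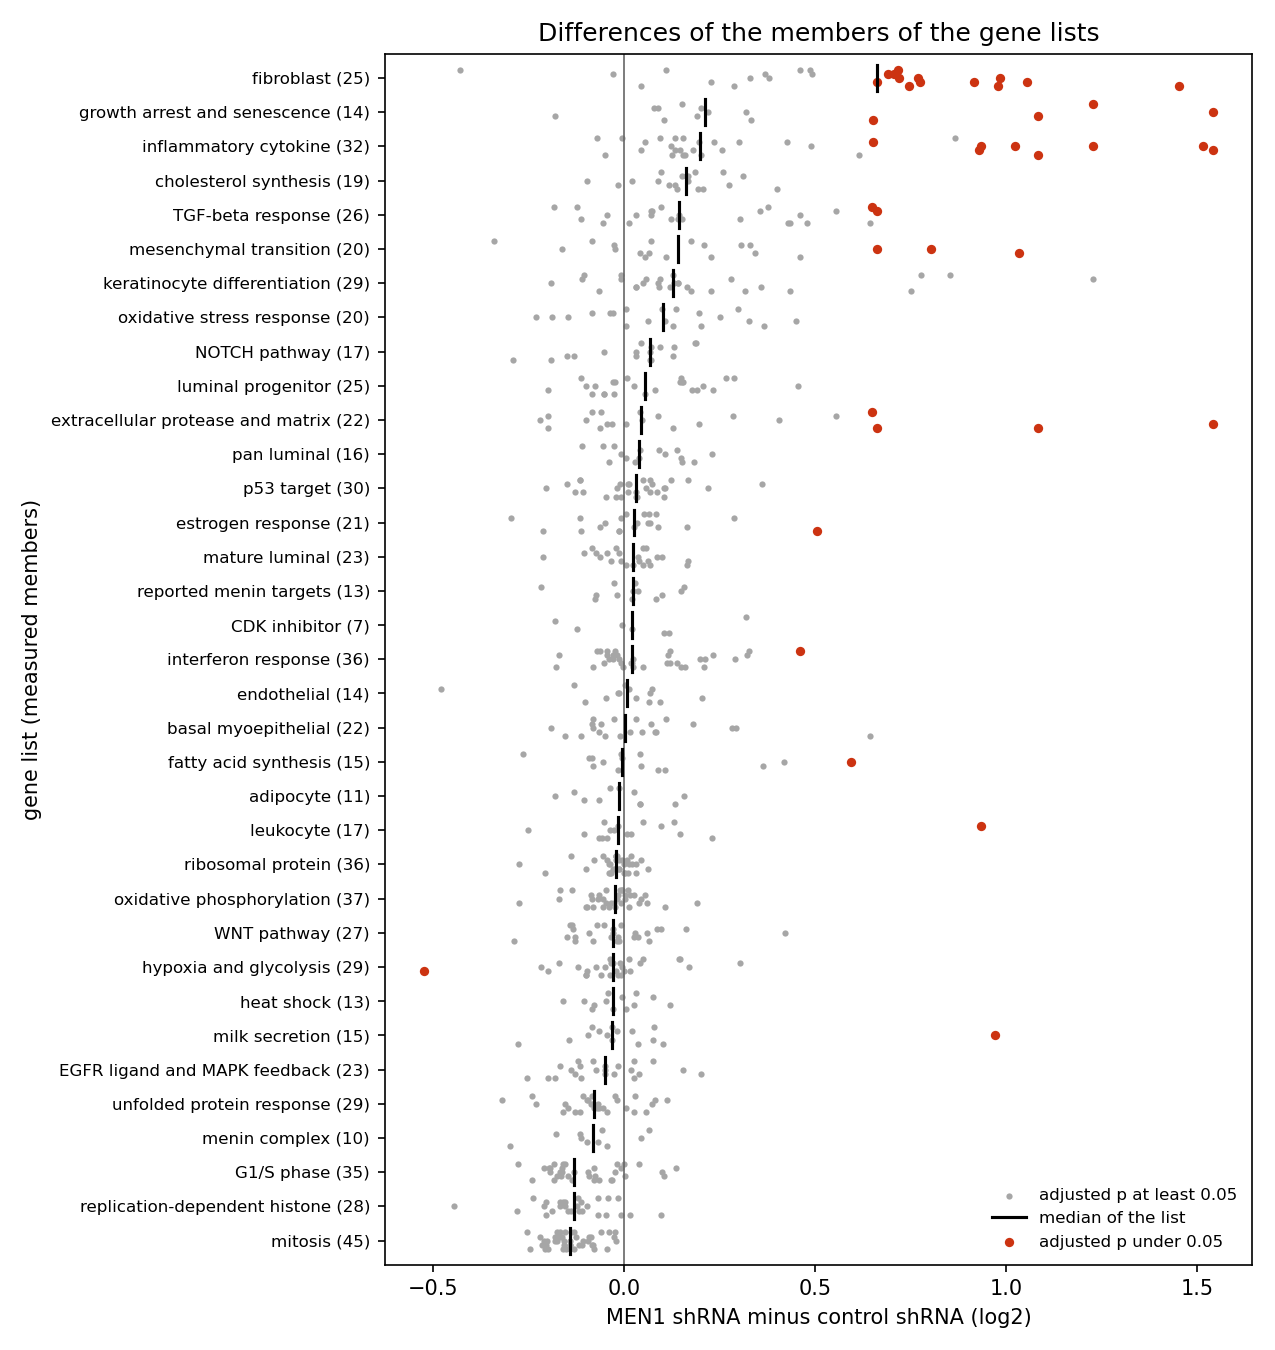
MEN1 shRNA minus control shRNA difference on the log2 scale (horizontal axis) for each measured member of the 35 gene lists (vertical axis, ordered by median). Red points passed an adjusted p of 0.05 over all genes in limma, grey points did not, and black bars are list medians, from -0.14 for mitosis to 0.66 for fibroblast genes.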

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

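The test in this part was chosen after the results were seen. Rows of the table that name several genes entered none of the comparisons above. In a limma fit over all rows that the annotation lists, 1 of 1754 such rows differed past the threshold (107 higher and 74 lower at an unadjusted p under 0.05), and 0 did so in a fit over all rows of the table (83 higher and 40 lower at an unadjusted p under 0.05). The log2 value of that 1 row was 7.78 ± 0.064 (SD, n = 2) in control shRNA and 8.40 ± 0.063 (SD, n = 2) in MEN1 shRNA, higher by 0.62 in limma (adjusted p = 0.0429), with no overlap between the groups. The row names 3 genes, so the signal belongs to no single gene.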

How the results depend on the processing

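The fits over all rows and the lists without shared genes were chosen after seeing the data, and the other settings before. The direction of MEN1 was the same in all 15 fits, though only quantile normalization and median centring could have reversed it. MEN1 has 1 row and its groups did not overlap, so the other fits had to keep its sign. MEN1 passed with an intensity trend (-0.30, adjusted p = 0.0140) and among genes above the median level (-0.30, adjusted p = 0.0122), where fewer genes were tested. Genes higher and lower numbered 67 and 6 in the reported fit, 340 and 162 with the trend and 105 and 19 with median centring. They numbered 212 and 117 above the median level, 113 and 26 above the 20th percentile and 113 and 23 at an adjusted p under 0.10. With limma's treat against a 1.2-fold change they were 12 and 0. At an unadjusted p under 0.05 they were 1060 and 1004, together 2064, where chance gives 921 for both directions together. A limma fit over all rows called 0 and 0 (788 and 650 at an unadjusted p under 0.05), and with a trend 46 and 5. Prior degrees of freedom were 2.35 over all rows against 3.57 over genes. With the replicate number as a block, which the labels do not describe as a pairing, 52 genes were higher and 2 lower (40 of the 67 and 1 of the 6 reported, with 8 of the 13 fibroblast genes), and 12 and 5 lists were called. Same-numbered arrays deviated from their group means with a correlation over genes of 0.145, and 2 pairs do not settle a pairing. Leaving out each array in turn gave 0 to 11 genes higher and 0 to 1 lower in limma, with the lone array assumed to vary like the other group. It also gave 10 to 17 genes at least 1.5-fold lower without overlap, against 7, and 4 to 8 lists lower, against 5. A lone array lies beyond 2 others by chance more often than 2 arrays do, so the 10 to 17 genes do not compare directly with 7. Genes at least 1.5-fold higher and lower without overlap numbered 32 and 0 above the median level, 3 lower above the 20th percentile, and 19 and 0 at 2-fold. Lists called higher and lower went from 12 and 5 to 0 and 0 with an estimated correlation and to 5 and 0 with fry (fibroblast, TGF-beta, protease and matrix, senescence and inflammatory). Quantile normalization, the mean of a gene's rows and the robust prior left each count within 1.5-fold, though the pan luminal list lost its call with the mean of a gene's rows (adjusted p = 0.0723), EGFR ligands and MAPK feedback were called lower with quantile normalization (adjusted p = 0.0413), and the robust prior was not run for lists. Among single named genes, 1708 comparisons with an alternative agreed in direction and side of the threshold, 117 passed newly, 170 no longer passed and 3 uncalled genes reversed when 1 array was left out: LEP ran from -0.035 to 0.35, PECAM1 from -0.21 to 0.0036 and CEL from -0.31 to 0.026. For list calls the numbers were 441, 6, 39 and 0, and 8 uncalled lists changed direction in at least 1 setting. The agreeing comparisons include genes and lists that passed in neither fit. Several settings cannot change a gene's difference, so part of the agreement is built in. Unless stated, the cause of a change was not tested. Signal over background is not in the table, so the level below which a dim gene has no signal is unknown.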

Other observations

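The tests of explanations in this part were all chosen after the results were seen. Outside the groups described so far, single genes of other lists changed without their lists. The secreted mucin-like MUCL1 rose by 0.97 from a log2 level of 11.13, while the casein CSN1S1 was at -0.28 and the milk secretion list had a median of -0.031 (camera, adjusted p = 0.960). The fatty acid desaturase FADS2 rose by 0.59, with GPAM at 0.42, FADS1 at 0.36 and the regulator SREBF1 at -0.27, and the fatty acid synthesis list had a median of -0.0051 (camera, adjusted p = 0.254). IGFBP4, a binding protein of insulin-like growth factors, rose by 0.51 among estrogen response genes, whose median was 0.027 (camera, adjusted p = 0.390). SLC2A3, which fell, was the 1 changed gene of 29 in the hypoxia and glycolysis list (median -0.029, camera, adjusted p = 0.186). Adjusted over the list alone, the higher and lower genes numbered 1 and 1 for milk secretion, 3 and 1 for fatty acid synthesis, 2 and 1 for estrogen response and 0 and 1 for hypoxia and glycolysis. Medians and means differed in sign for the milk secretion, fatty acid, leukocyte and endothelial lists.

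The signalling, arrest and housekeeping lists of this paragraph held 0 genes past the threshold over all genes in limma and were not called by camera in the reported fit. Camera called EGFR ligands and MAPK feedback lower with an intensity trend (adjusted p = 0.0212), with quantile normalization (adjusted p = 0.0413), without control shRNA replicate 1 (adjusted p = 0.0164) and without MEN1 shRNA replicate 2 (adjusted p = 0.0205). Without control shRNA replicate 1 it also called ribosomal proteins (adjusted p = 0.0333) and oxidative phosphorylation (adjusted p = 0.0255) lower. Adjusted over the list alone, the receptor NOTCH1 was lower (-0.29) in the NOTCH pathway, and in the WNT pathway the ligand WNT5A was higher (0.42) and the inhibitor SFRP1 lower (-0.29). In the other lists of this paragraph 0 genes passed when adjusted over the list alone. Medians were 0.068 for the NOTCH pathway (adjusted p = 0.574), -0.028 for the WNT pathway (adjusted p = 0.304), -0.050 for EGFR ligands and MAPK feedback (adjusted p = 0.0582), 0.022 for CDK inhibitors (adjusted p = 0.596), 0.031 for p53 targets (adjusted p = 0.254) and 0.024 for reported menin targets (adjusted p = 0.596). Of 22 reported menin targets 13 were measured, since CDKN2C, HOXC6 and the HOXA genes of the list had no row of their own. The median of that list does not cover them. Of 7 CDK inhibitors 4 had a positive and 3 a negative difference, with CDKN2B at 0.32 and CDKN2A at -0.18. Of 30 p53 targets 19 were positive and 11 negative, with TP53I3 at 0.36. Ribosomal proteins had a median of -0.020 (adjusted p = 0.254), oxidative phosphorylation -0.025 (adjusted p = 0.228) and heat shock genes -0.030 (adjusted p = 0.451).

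Fibroblast genes were higher in MEN1 shRNA, and 2 explanations were tested. A loss of epithelial features across the whole culture would lower most pan luminal genes, and 1 of 16 was lower without overlap while 9 were higher, which argues against it, although a change in few cells stays open. A larger share of fibroblasts and an effect of MEN1 or of the hairpin in the epithelial cells cannot be told apart: 23 of the 25 markers were higher without overlap, but that count restates the pattern and favours neither. The abundant collagens COL1A1 (9.69 in control shRNA, higher by 0.75) and COL1A2 (9.16, higher by 0.92), named after their values were seen, were among them, but FBLN1 was at -0.43. Of the 25 genes, 13 lay above the median gene in control arrays and 5 are in another list. The cells were sorted from tissue by CD49f and EpCAM, which does not show whether the cultures held fibroblasts when RNA was taken.

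Mitosis genes were lower in MEN1 shRNA, and dilution of the epithelial RNA by other cells was tested as the cause. Dilution would lower pan luminal genes as much, unless those genes rose for another reason. Their median was 0.040 (95% bootstrap interval over genes -0.0072 to 0.137) against -0.14 (-0.16 to -0.13) for mitosis. The intervals treat genes as independent and leave out the spread between arrays. Without overlap, 1 of 16 pan luminal genes was lower, against 39 of 45 mitosis genes. These values argue against dilution as the only cause. Slower division, from the hairpin or from culture conditions that differ by group, may lower them and cannot be separated by this design.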
